A study of Mus musculus with 12 samples.

How the data were processed

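PolyA RNA from muscle of mice given PBS or LLC cells and open chromatin of C2C12 myotubes kept in control or C26-conditioned medium were each measured in 3 libraries per group, 12 in all. The labels do not name the muscle, and they give the cell type of the cultured samples as myoblast although the titles speak of myotubes. Per the submitters' processing notes, HISAT2, HOMER, DESeq2, Bowtie2 and MACS2 were used with the builds GRCm38 and mm10, and their versions and roles are not given in the sources used here. Trimming, duplicate handling, the Tn5 offset and the peak threshold are likewise not given in the sources used here.

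The RNA values are FPKM made by the authors with HOMER, per the file headers, from exons of RefSeq genes in mm10 with reads of both strands counted and 1 transcript kept per gene. Genes that overlap on opposite strands cannot be separated in such values, and reads of near-identical genes may fall on either copy. The ATAC values are signal, deposited as tags per peak scaled to 10 M tags per library, per the file headers, over a merged list of peaks annotated with HOMER in mm10. Every peak came from at least 2 of the 6 per-library peak lists, and 0 from just 1. Products of each ATAC value and the library total fell on whole steps for 100% of values within a tolerance of 0.1. Products of FPKM and gene length did so for 100% of the values checked. Those were genes under 3000 bp, above 0.02 FPKM and with at most 20 steps. The steps gave back the reads and the depth, and products of longer or higher genes were rounded to the nearest step. Recovered read ends in genes were 25.7, 31.9 and 29.4 M in PBS 1 to 3 and 28.7, 29.1 and 32.5 M in LLC 1 to 3. No library was a copy of another. All 12 sample columns were used, and 0 were left over. Of 38244 peaks, with a median width of 520 bp, 79 have a gene name turned into a date and 15 have no distance to a gene; these stayed in the tests of all peaks.

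From these values log2(value + 1) was computed, which understates the fold of genes near 0. Genes with a mean of at least 1 FPKM (12981 of 20194) and peaks with a mean of at least 5 (37358 of 38244) were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Means are arithmetic means with the sample SD; SE is that of the limma log2 difference. Recovered reads were also tested with the quasi-likelihood model of edgeR 4.0.16. Because the median ATAC change was not 0, a second fit used median-of-ratios scaling, with factors from peaks above 0 in every library, and another used quantile normalization. Plots were made with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

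The pipeline was tested on simulated data with the means and dispersions of the recovered reads. Among 12768 genes it recovered 1 of 99 with a log2 change of 1 and 42 of 100 with a change of 2, with 2 false calls. Among 37337 peaks it recovered 24 and 69 of 100, with 0 false calls. A count of 0 called genes therefore leaves room for changes of these sizes. The simulation ran only the fit without scaling and drew each gene or peak independently. Its false calls therefore do not extend to the scaled ATAC fit or to variation shared between genes of a library.

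Before the values were seen, 36 gene lists with 663 members were written, and 659 members were found in the RNA table. They were tested with camera at an inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Members were also tested with p adjusted over the list alone. For 21 lists the promoter peak with the highest mean, within 1000 bp of the annotated start (3000 bp as an alternative), stood for each gene. Shares of called promoter and distal peaks were compared with Fisher's exact test, and log2 changes of the assays with Spearman's rho across genes.

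The genes named in the text follow a rule also written before: in the RNA, the 12 largest rises and falls past the threshold (0 genes), up to 4 members of each list with the smallest p, and Ddit4, Fbxo32, Trim63, Atf4, Dnmt3a, Mat2a, Ahcy, Mtr, Foxo1 and Fkbp5. In the ATAC it takes the 10 largest rises and falls, all peaks at Ddit4, up to 3 promoter peaks per list and the promoters of the genes just given. Grrp1, Camp, Bglap, Ibsp, Krt8, Krt10 and Krt18, and 8 lists of marker genes for marrow, blood, bone and epithelium, were chosen after values had been seen.

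Alternatives tried were pseudocounts of 0.1 and 0.5 (RNA) and 0.5 and 5 (ATAC), no filter, a mean of at least 5 FPKM or 20 tags, TPM, median-of-ratios and quantile scaling, no trend, an adjusted p under 0.1, a log2 change of at least 1, replicate numbers as a term, and leaving out each library in turn. Scores of marrow or skin genes as covariates were added later. A motif search in changed peaks was planned and not analysed here, since it needs the genome sequence.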

Results

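Cachexia is the loss of muscle and fat that accompanies some cancers, and the 12 mouse libraries addressed how gene expression and chromatin respond to it in muscle cells. RNA-seq of polyA RNA was made from muscle of C57BL/6 mice, with 3 libraries after PBS and 3 after 500000 Lewis lung carcinoma (LLC) cells under the skin and tissue taken on day 22. ATAC-seq, which marks open chromatin by where the Tn5 transposase cuts, was made from myotubes of C2C12, a mouse myoblast line that fuses into multinucleate muscle cells. There were 3 control libraries and 3 libraries after 24 hours in medium conditioned by Colon-26 (C26) cells, a mouse colon carcinoma line. The RNA libraries held 17.0, 18.9 and 17.3 M tags (M, 10 to the power of 6) in PBS 1 to 3 and 17.9, 17.3 and 20.1 M in LLC 1 to 3. The ATAC libraries held 11.2, 14.8 and 10.1 M tags in controls 1 to 3 and 12.8, 14.4 and 18.2 M in C26 medium 1 to 3. Nothing in the labels says that the 3 libraries of a group came from separate animals or cultures, and the C2C12 cells were seeded in triplicate. The p-values therefore measure the spread between these samples, which may be technical.

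The first comparison, LLC against PBS muscle, bears on REDD1, the protein named in the series title. Ddit4, which encodes this inhibitor of mTORC1 signalling, was at 17.1 ± 4.64 FPKM in LLC muscle and 7.52 ± 2.18 FPKM in PBS muscle (SD, n = 3). All 3 LLC libraries, at 12.1, 17.9 and 21.2 FPKM, lay above the 3 PBS libraries, at 5.27, 7.68 and 9.62 FPKM. The Ddit4 transcript NM_029083 lies on chromosome 10 from 59949675 to 59951770 (mm10). Of 26 REDD1, mTORC1 and FOXO regulators 19 were above 0, with a median log2 difference of 0.16. Camera called the list higher (adjusted p of 0.00129), a call lost at adjusted p = 0.522 with an estimated correlation and 0.230 with fry, a test of whether a list moves one way on balance. Klhl38, a target of FOXO factors, had the smallest p in that list, at 26 ± 8.63 FPKM in LLC and 7.80 ± 1.17 in PBS muscle. Pik3ip1, an inhibitor of PI3 kinase, was at 34.0 ± 4.17 against 22.3 ± 1.69 FPKM. Foxo1, which drives atrophy genes, was at 8.01 ± 1.97 against 6.04 ± 0.62 FPKM, with overlapping groups. The limma log2 difference of Ddit4 was 1.08 (SE 0.28) with an adjusted p of 0.410 over all genes tested, so the gene did not pass. In the list 1 member rose when adjusted over the list alone. Without PBS 3 the list had an adjusted p of 0.0564.

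Of 20 ubiquitin ligases of muscle atrophy 15 were above 0, with a median log2 difference of 0.14. Camera called the list higher (adjusted p of 0.0348), a call lost at adjusted p = 0.522 with an estimated correlation and 0.261 with fry, and kept in 2 of 6 fits with 1 library left out. Fbxo32, which encodes atrogin-1, was at 62.2 ± 27.4 FPKM in LLC and 19.9 ± 4.41 in PBS muscle (SD, n = 3). Trim63, which encodes MuRF1, was at 129 ± 53.3 against 54.2 ± 4.70 FPKM. In LLC 1 these genes stood at 31.8 and 69.1 FPKM, and in LLC 3 at 85.0 and 172 FPKM. Neither passed over all genes, with limma log2 differences of 1.5 (SE 0.39, adjusted p = 0.410) and 1.14 (SE 0.35, adjusted p = 0.489). When adjusted over the list alone 0 members rose, and 2 had an unadjusted limma p under 0.05. The call was lost without PBS 2 (adjusted p = 0.0607), PBS 3 (0.348), LLC 2 (0.0599) or LLC 3 (0.132), and with scaling to TPM (0.0683) or by median of ratios (0.0691).

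**Figure D1:**
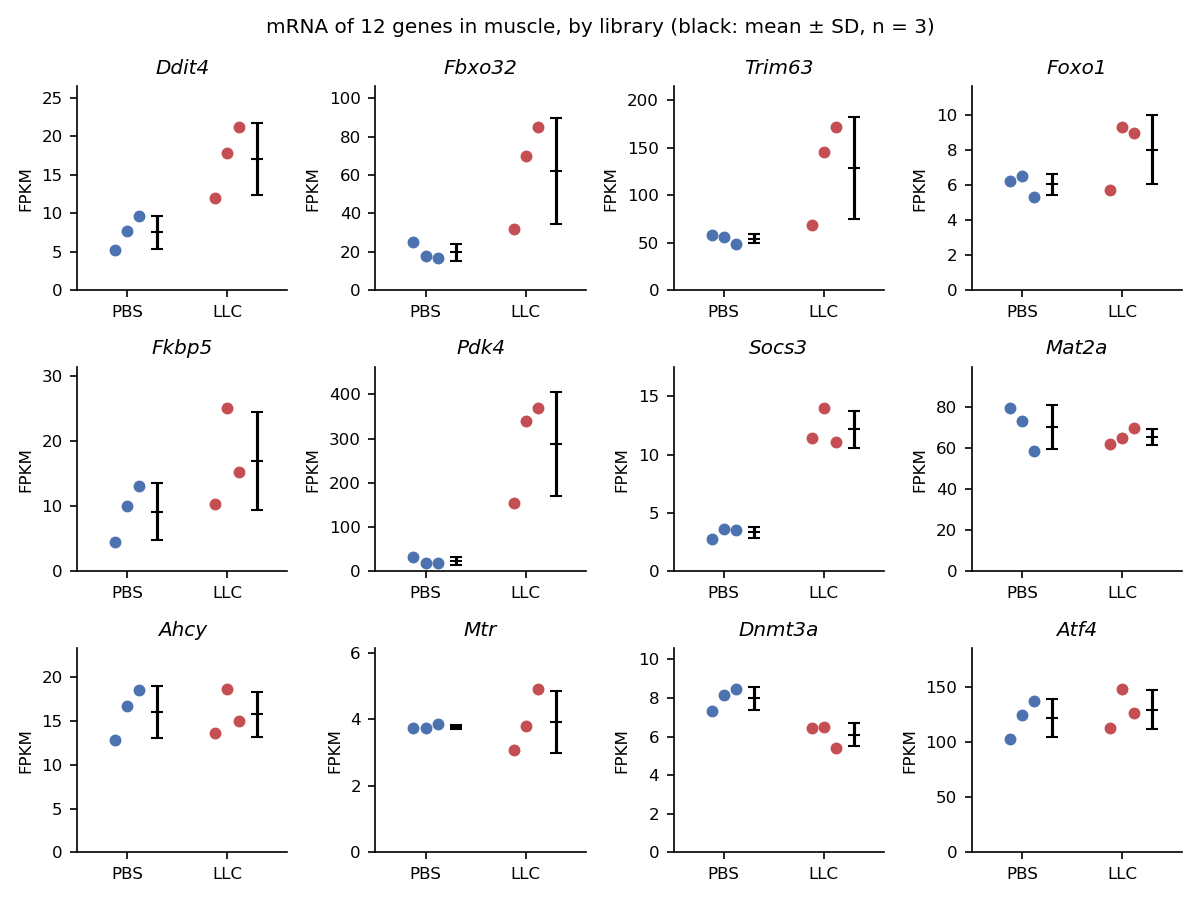
FPKM of 12 genes in each muscle library, with PBS in blue, LLC in red and the mean ± SD (n = 3) in black. Ddit4 lay between 5.27 and 9.62 FPKM in PBS and between 12.1 and 21.2 FPKM in LLC muscle. Foxo1, Fkbp5, Mat2a, Ahcy, Mtr and Atf4 overlapped between the groups.

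For the proteasome, autophagy and lysosome, and heat shock lists camera gave calls higher, with adjusted p-values of 0.000194, 0.00423 and 0.00129. All 3 calls were lost at adjusted p = 0.522, 0.465 and 0.522 with an estimated correlation, and at 0.261, 0.230 and 0.261 with fry. Of 32 proteasome subunits 31 were above 0, with a median log2 difference of 0.15, led by Psmd7 at 93.5 ± 9.19 FPKM in LLC and 68.8 ± 8.62 in PBS muscle (SD, n = 3). Autophagy and lysosome genes had 20 of 28 members above 0, led by Gabarapl1, which marks autophagosomes, at 50.7 ± 5.88 against 30.5 ± 1.27 FPKM. Sqstm1, the autophagy receptor p62, was at 297 ± 52.4 against 190 ± 18.9 FPKM. Heat shock genes and chaperones had 14 of 17 members above 0, with the small heat shock protein gene Hspb1 at 179 ± 33.9 against 85.6 ± 5.49 FPKM. Hspa1a and Hspa1b, near-identical genes whose reads can be split between them, were at 5.93 ± 3.26 against 1.254 ± 0.257 and at 6.26 ± 2.60 against 1.37 ± 0.55 FPKM. Adjusted over the list alone, 0 proteasome, 1 autophagy and 4 heat shock members rose.

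Of 24 genes of fatty acid oxidation and PPAR targets 22 were above 0, with a median log2 difference of 0.52. Camera gave this list the smallest adjusted p of all lists, 4.46e-16, a call lost at adjusted p = 0.0739 with an estimated correlation and kept with fry (0.00286). Acot2, a mitochondrial thioesterase, was at 5.81 ± 0.642 FPKM in LLC and 1.61 ± 0.0624 in PBS muscle (SD, n = 3), though its reads can be shared with the paralog Acot1. Fabp3, the fatty acid carrier of muscle, was at 348 ± 54.9 against 105 ± 25.5 FPKM, and Plin5, which coats lipid droplets, at 9.45 ± 1.26 against 3.28 ± 0.446 FPKM. All 20 glucocorticoid-induced genes were above 0, with a median of 0.69. Camera called them higher (adjusted p of 9.82e-10), a call lost at adjusted p = 0.465 with an estimated correlation and 0.151 with fry. Among them Pdk4, which blocks glucose oxidation, was at 288 ± 117 against 23.8 ± 8.47 FPKM, and Cdkn1a, a cell cycle inhibitor, at 16.5 ± 1.62 against 8.29 ± 1.22 FPKM. Fkbp5, a common read-out of glucocorticoid exposure, was at 16.9 ± 7.51 against 9.19 ± 4.38 FPKM, with overlapping groups. Adjusted over the list alone, 11 fat genes and 5 glucocorticoid genes rose.

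Camera called the IL-6 and STAT3 response, endothelial, and smooth muscle and pericyte lists higher, with adjusted p-values of 1.83e-09, 7.18e-10 and 0.00989. All 3 calls were lost at adjusted p = 0.465, 0.280 and 0.522 with an estimated correlation, and with fry the endothelial call held (0.0169) while the others did not (0.151 and 0.327). In the IL-6 and STAT3 response list 16 of 20 members were above 0, with a median log2 difference of 0.87. Socs3, which dampens STAT3 signalling, was at 12.1 ± 1.61 FPKM in LLC and 3.34 ± 0.469 in PBS muscle (SD, n = 3), and Osmr, the oncostatin M receptor, at 11.3 ± 2.03 against 3.28 ± 0.744 FPKM. Of 11 endothelial markers 10 were above 0, with a median of 0.81, including the junction genes Pecam1 at 81.7 ± 9.85 against 34.4 ± 3.15 FPKM and Cldn5 at 37.0 ± 2.56 against 11.2 ± 2.80 FPKM. All 8 smooth muscle and pericyte markers were above 0, with a median of 0.27 and Myh11 at 16.9 ± 2.65 against 11.4 ± 1.64 FPKM. Adjusted over the list alone, 7 IL-6 genes, 8 endothelial genes and 0 smooth muscle genes rose. The smooth muscle call was lost without PBS 3 (0.141) or LLC 1 (0.135) and with TPM (0.0577).

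All 13 slow-fibre contractile genes were above 0, with a median log2 difference of 1.19. The groups overlapped in the mean log2(FPKM + 1) of the list, taken relative to its mean over the PBS libraries. That mean was 0.872, -0.431 and -0.440 in PBS 1 to 3, and 1.92 and 1.64 in LLC 1 and LLC 2. LLC 3 lay below PBS 1, so 2 LLC libraries lay above all PBS libraries. Camera called the list higher (adjusted p of 2.99e-08), a call lost at adjusted p = 0.465 with an estimated correlation and 0.230 with fry. Myh7, the slow myosin heavy chain, was at 56.1 ± 28.1 FPKM in LLC and 11.5 ± 12.5 in PBS muscle (SD, n = 3), and 25.9 FPKM in PBS 1 nearly reached the 27.8 FPKM of LLC 3. Csrp3, a Z-disc protein, was at 184 ± 93.4 against 39.6 ± 5.54 FPKM. When adjusted over the list alone 1 member rose. The fast-fibre list was not called (camera adjusted p = 0.871): its median was 0.11 and its mean 0.04 while the test pointed down, and with quantile normalization it was called higher (0.0175). Casq1, the calcium store protein of fast fibres, was at 861 ± 131 against 1338 ± 269 FPKM, while the fast myosin gene Myh2 was at 171 ± 42.3 against 108 ± 31.0 and Actn3, of the fast-fibre Z-disc, at 2122 ± 343 against 1730 ± 344 FPKM, both with overlapping groups.

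Camera called the extracellular matrix and tendon lists lower, with adjusted p-values of 1.23e-07 and 9.35e-08. Both calls were lost at adjusted p = 0.522 and 0.465 with an estimated correlation, and at 0.418 and 0.249 with fry. Of 26 extracellular matrix genes 21 were below 0, with a median log2 difference of -0.43. Col1a1 and Col1a2, the chains of type I collagen, were at 51.9 ± 23.5 and 84.7 ± 42.8 FPKM in LLC and 227 ± 93.6 and 345 ± 132 FPKM in PBS muscle (SD, n = 3). All 7 tested tendon markers were below 0, with a median of -2.32: Tnmd, a tenocyte membrane protein, was at 4.12 ± 4.54 against 21.3 ± 4.42 FPKM and Chad, a cartilage and tendon matrix gene, at 14.5 ± 17.9 against 65.5 ± 11.6 FPKM. The osteoblast genes Bglap and Ibsp, which also make or bind bone matrix, stood at 0, 84.3 and 52.2 and at 0.197, 34.6 and 34.1 FPKM in PBS 1 to 3, and at 13.5, 1.59 and 0 and at 14.8, 11.7 and 0.051 FPKM in LLC 1 to 3. Adjusted over the list alone, 2 matrix genes and 4 tendon genes fell. The matrix call was lost without PBS 1 (adjusted p = 0.0843).

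Genes of blood formation differed more between libraries than between the groups. The neutrophil granule gene Camp stood at 8.14, 538 and 1151 FPKM in PBS 1 to 3 and at 426, 779 and 6.77 FPKM in LLC 1 to 3, and the alarmin gene S100a9 at 26, 2342 and 4324 and at 2293, 3999 and 95.2 FPKM. The first principal component, with 60.9% of the variance, placed PBS 1 (-63.7) and LLC 3 (-41.0) at one end and PBS 3 (55.5) and PBS 2 (30.3) at the other. The neutrophil list was not called (camera adjusted p = 0.899, median log2 difference 0.010, mean 0.08, test down), though without LLC 3 it was called higher (0.0173). Cell cycle, erythroid and interferon-stimulated genes were called lower, with all 18 cell cycle genes, all 9 erythroid genes and 16 of 21 interferon genes below 0 and medians of -0.73, -0.97 and -0.20. Camera gave adjusted p-values of 0.0168, 0.0370 and 0.0370, and the calls were lost at adjusted p = 0.722, 0.722 and 0.722 with an estimated correlation and 0.832, 0.792 and 0.832 with fry. Slc4a1, the anion exchanger of red cells, was at 26.6 ± 35.5 FPKM in LLC and 115 ± 104 in PBS muscle (SD, n = 3), and the replication gene Mcm2 at 7.92 ± 5.24 against 19.4 ± 15.5 FPKM. In the interferon list the smallest p was that of Gbp2, a guanylate-binding protein gene that pointed the other way, at 9.50 ± 1.28 against 7.08 ± 0.664 FPKM without overlap of the groups (unadjusted p = 0.0356). Ifit1, an antiviral gene, was at 2.23 ± 0.43 against 3.16 ± 1.12 FPKM, with overlapping groups. The values of Hba-a1, Hba-a2 and the other globin genes cannot be assigned to single copies. Adjusted over the list alone, 0 members of each fell. Without PBS 3 the 3 lists had adjusted p-values of 0.541, 0.541 and 0.683, and leaving out PBS 2 (0.0815, 0.0893 and 0.0815) ended the calls too. Further losses were cell cycle without LLC 3 (0.304) and with a pseudocount of 0.1 (0.0515), erythroid without LLC 1 (0.133) or LLC 3 (0.122), without a filter (0.0633) and with median-of-ratios (0.0585) or quantile (0.0567) scaling, and interferon without LLC 2 (0.153), without a filter (0.0703) and with a mean FPKM of at least 5 (0.274).

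All 4 tested members of the epithelial and tumour-cell list were above 0, with a median log2 difference of 1.99 and a camera adjusted p of 0.0178. The call was lost at adjusted p = 0.522 with an estimated correlation and 0.429 with fry. The epidermal keratin Krt14 stood at 126, 10.1 and 34.8 FPKM in LLC 1 to 3 and at 0, 0.807 and 13.8 FPKM in PBS 1 to 3. Krt10, of the outer epidermis, stood at 758, 28.3 and 306 FPKM and at 0.452, 2.93 and 44.5 FPKM in the same order. The keratins of simple epithelium, Krt8 and Krt18, had means of 0.382 and 0.510 FPKM in LLC muscle. Adjusted over the list alone 0 members rose, and the call was lost without PBS 1 (0.0786), PBS 2 (0.0815) or LLC 1 (0.135) and with the skin covariate (0.604), a score of other epidermal genes.

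**Figure D2:**
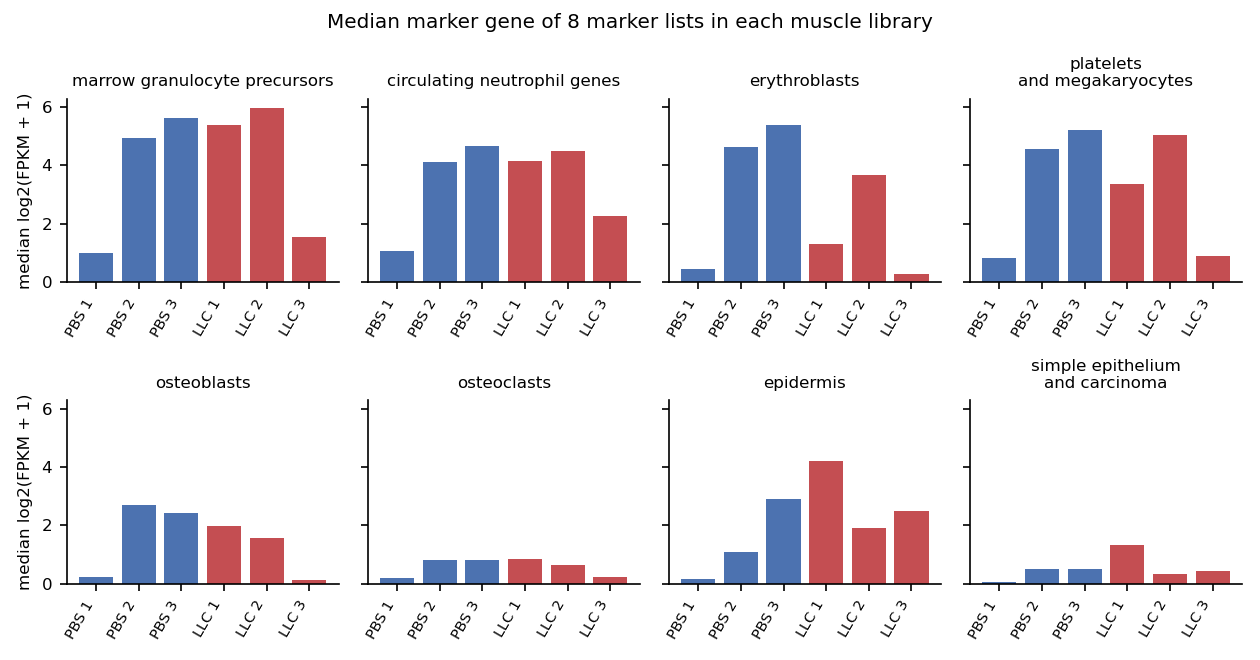
Median log2(FPKM + 1) of 8 lists of tissue marker genes in each muscle library, with PBS in blue and LLC in red. The marrow granulocyte precursor median was 0.99 in PBS 1 and 5.64 in PBS 3, and 5.98 in LLC 2 and 1.53 in LLC 3.

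The methionine cycle, named in the series title, was not called as a list: 14 of 21 tested genes were below 0, the median log2 difference was -0.026 and the camera adjusted p was 0.124. Mat2a, which makes S-adenosylmethionine, was at 65.7 ± 3.91 FPKM in LLC and 70.5 ± 10.7 in PBS muscle (SD, n = 3). Ahcy, which clears S-adenosylhomocysteine, was at 15.7 ± 2.58 against 16.0 ± 2.94 FPKM, and Mtr, methionine synthase, at 3.93 ± 0.929 against 3.78 ± 0.0647 FPKM. Gamt, which uses S-adenosylmethionine to make creatine, was at 7.11 ± 0.721 against 11.9 ± 3.04 FPKM, the smallest p of the list (limma adjusted p = 0.524 over all genes). Dnmt3a, a DNA methyltransferase, was at 6.10 ± 0.607 against 7.98 ± 0.60 FPKM (limma adjusted p = 0.577), and the 12 DNA methylation genes had a median of -0.13 and an adjusted p of 0.241. ATF4 and integrated stress response genes had a median of 0.10 and an adjusted p of 0.436, with Chac1, an ATF4 target that degrades glutathione, at 83.1 ± 23 against 31.6 ± 9.15 FPKM and Atf4 itself at 129 ± 17.7 against 122 ± 17.3 FPKM. Folate one-carbon genes had a median of -0.23 and an adjusted p of 0.0730, with 13 of 17 below 0 and 4 above. Gcsh was at 22.8 ± 0.688 against 27.8 ± 2.04 FPKM, while Amt was higher, at 1.77 ± 0.107 against 1.195 ± 0.211 FPKM. The folate list was called lower in 4 other fits (adjusted p from 0.0305 to 0.0465). The methionine list was called lower without LLC 3 (0.00545) or PBS 3 (0.0197), and its adjusted p without PBS 1 was 0.814.

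Among the other lists that camera did not call, Inhbb, an activin subunit gene of the myostatin, activin and BMP pathway, was at 4.74 ± 1.47 FPKM in LLC and 1.08 ± 0.254 in PBS muscle (SD, n = 3); that list had a median log2 difference of 0.10 and an adjusted p of 0.0637, with 1 member higher when adjusted over the list alone. It was called higher with median-of-ratios scaling (0.0431), with quantile normalization (0.0262), with the replicate number as a block (0.0405), with the skin covariate (0.00636), without PBS 1 (0.00288) and without LLC 2 (0.0464). Medians and camera adjusted p-values were 0.12 and 0.13 for the circadian clock, 0.15 and 0.12 for myogenic factors, and 0.17 and 0.179 for the denervation response. Myod1, a myogenic transcription factor, was at 6.09 ± 1.49 against 10.4 ± 2.47 FPKM, while Myog, another such factor, was at 3.49 ± 1.32 against 1.83 ± 0.312 with overlapping groups and the growth factor gene Igf2 at 6.49 ± 0.37 against 5.28 ± 0.396 FPKM. The myogenic list was called higher without PBS 1 (0.00901), without LLC 1 (0.0193), without a filter (0.0319) and with the skin covariate (9.63e-05). The circadian list was called higher without PBS 1 (0.00162) or LLC 2 (0.0198) and with the skin covariate (0.0154), and the denervation list without PBS 1 (0.0289) and with the skin covariate (0.0193). For denervation the acetylcholine receptor gene Chrna1 was at 5.28 ± 1.16 against 2.94 ± 0.733 FPKM. NF-kB targets had a median of 0.13 and an adjusted p of 0.137, with 13 of 18 above 0 and 5 below. The adhesion gene Icam1 was at 8.05 ± 1.85 against 3.75 ± 0.775 FPKM. Tnfaip2 was lower, at 20.8 ± 6.30 against 34.5 ± 10.8 FPKM, with overlapping groups. Oxidative phosphorylation had 0.030 and 0.827, and glycolysis -0.0042 and 0.827 with a mean of 0.02; glycolysis was called higher without PBS 1 (0.0227) and lower without PBS 3 (0.03). Of the cell type lists, B cells had a median of -0.97 (adjusted p = 0.0595), adipocytes 0.38 (0.12), macrophages -0.10 (0.163), fibro-adipogenic progenitors -0.21 (0.267), T and NK cells 0.012 (0.341, mean -0.04) and Schwann cells -0.012 (0.975, mean 0.02, test down). In other fits B cells were called lower with TPM (0.0231), with the number as a block (0.00268), with the skin covariate (0.0183) and without PBS 1 (0.0256) or LLC 3 (3.08e-06). Adipocytes were called higher without PBS 1 (0.0418), LLC 1 (0.0025) or LLC 2 (0.0151) and with the skin covariate (0.0039). Macrophages were called lower with quantile normalization (0.0446) and without PBS 1 (0.00901), T and NK cells without LLC 3 (0.00186), and progenitors (0.00014) and Schwann cells (0.0437) without PBS 3. The lipid droplet gene Plin4 was at 61.7 ± 25.7 against 26.5 ± 6.44 FPKM.

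**Figure D3:**
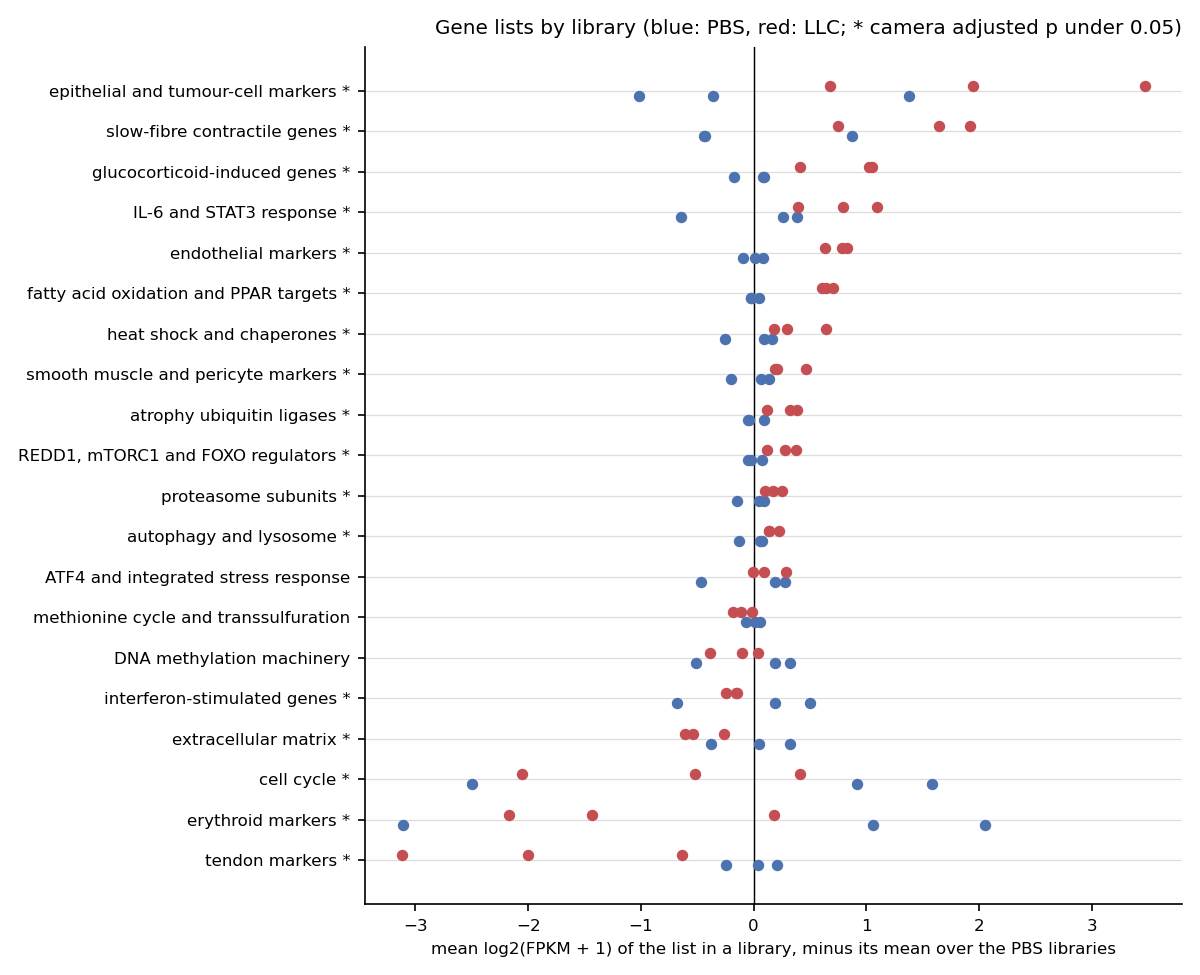
Mean log2(FPKM + 1) of each gene list in a muscle library, minus its mean over the PBS libraries, with PBS in blue and LLC in red. The 3 LLC libraries lay at 0.64, 0.61 and 0.70 for fatty acid oxidation and at -0.64, -2 and -3.12 for tendon markers.

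Over all 12981 genes tested, 0 were higher and 0 lower at a limma adjusted p under 0.05, and edgeR on the recovered reads also gave 0. At an unadjusted p under 0.05 limma counted 991 genes, 755 higher and 236 lower, and edgeR 932. In every list the count over all genes was therefore 0. The smallest limma adjusted p, 0.0573, was that of Grrp1, a gene named here after its values were seen, at 25 ± 3.12 FPKM in LLC and 4.64 ± 0.486 in PBS muscle (SD, n = 3). The groups did not overlap in 1745 genes (13.4%), where chance gives 10%. By camera 12 of 36 lists were higher and 5 lower, and 0 of either with an estimated correlation.

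The second comparison, C26 medium against control myotubes, measured how accessible each of 37358 tested peaks was. Chromatin opened most at sites far from promoters. The largest rise lay between genes on chromosome 7 (128307800 to 128308268, mm10; nearest gene BC017158), at 39.1 ± 0.280 tags per 10 M after C26 medium and 1.23 ± 0.205 in controls (SD, n = 3). An intergenic peak on chromosome 1 (150015816 to 150016354), at -54795 bp from the start of Pla2g4a, the gene of the phospholipase that releases arachidonic acid, was at 34.9 ± 4.06 against 1.82 ± 1.30. The largest fall was an intergenic peak on chromosome 8 (103813972 to 103814759; nearest gene 4933400L20Rik), at 4.90 ± 2.25 against 54.7 ± 24.1. Falls also included an intronic peak of Nkd1, a brake on Wnt signalling, on chromosome 8 (88555451 to 88556061), with a scaled log2 change of -2.08 (SE 0.26). The median log2 change of all tested peaks was -0.54, and changes are given relative to it, after median-of-ratios scaling, where a log2 value is called scaled. The scaled changes of these first 3 peaks were 4.56 (SE 0.32), 4.09 (SE 0.34) and -2.75 (SE 0.26), with limma adjusted p-values on the deposited values of 3.90e-14, 1.78e-11 and 3.00e-10.

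On the deposited values limma called 428 peaks higher and 704 lower (37.8% higher), and after median-of-ratios scaling 6368 higher and 4753 lower (57.3% higher). Scaling kept 1131 of the 1132 deposited calls. On the deposited values the groups did not overlap in 13899 peaks (37.2%), where chance gives 10%. That count includes the shift common to all peaks, a median log2 change of -0.54, and does not separate changes of single peaks from it. Tags in peaks were 27.0, 13.1 and 17.9% of the library in controls 1 to 3 and 13.0, 12.0 and 13.5% after C26 medium. Without control 2, 748 peaks were higher and 19854 lower on the deposited values; without control 1 the counts were 1954 and 2617, and without each other library they lay between 92 and 142 and between 32 and 51. After scaling, leaving out any 1 library gave 5143 to 5770 higher and 3189 to 4206 lower.

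Promoter and distal peaks behaved differently. Among 10777 promoter peaks, within 1000 bp of a transcription start, 5 (0.0464%) were higher on the deposited values, against 423 (1.59%) of 26573 distal peaks. The odds ratio was 0.0287 (Fisher's exact test over peaks, two-sided p = 6.05e-55, treating peaks as independent). Lower calls were 104 (0.965%) at promoters and 600 (2.26%) at distal peaks, an odds ratio of 0.422 (Fisher's exact p = 1.10e-18). After scaling the direction of this last ratio turned: 2288 promoter peaks (21.2%) and 2465 distal peaks (9.28%) were lower, an odds ratio of 2.64 (Fisher's exact p = 2.95e-200). Higher calls after scaling were 270 (2.51%) and 6097 (22.9%), an odds ratio of 0.0863. The median scaled change was -0.16 at promoters and 0.09 at distal peaks. Promoter peaks held 43.3, 42.8 and 43.6% of the tags in peaks in controls 1 to 3 and 38.9, 38.6 and 37.9% after C26 medium.

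**Figure D4:**
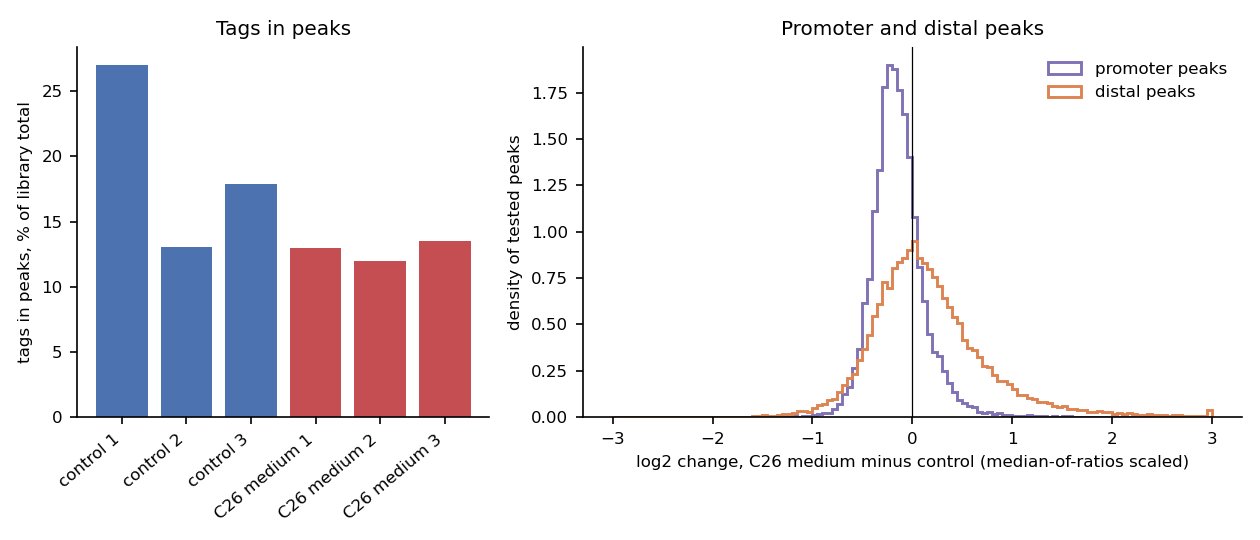
Tags in peaks as a percentage of all tags in each ATAC library (left), and the distribution of scaled log2 changes of promoter and distal peaks (right). Control 1 held 27.0% of its tags in peaks, and the promoter curve has its median at -0.16 and the distal curve at 0.09.

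Ddit4 was the nearest gene of 8 tested peaks on chromosome 10, and none of them was called on the deposited values by limma (adjusted p from 0.115 to 0.894). Its promoter peak (59951527 to 59952505) held 106 ± 6.17 tags per 10 M after C26 medium and 190 ± 58.5 in controls (SD, n = 3), a scaled log2 change of -0.27 (SE 0.09). The intergenic peak at 59947386 to 59948002, 4076 bp downstream of the start, had a scaled change of 0.77 (SE 0.13), and the one at 59932561 to 59932965 had 0.60 (SE 0.13). After scaling, limma called these 2 peaks higher (adjusted p = 6.80e-06 and 0.000292) and the promoter peak lower (0.02). With quantile normalization the promoter peak had an adjusted p of 0.0573, while both distal calls held. Without control 2, control 3 or C26 medium 3, 0 peaks were lower at Ddit4 after scaling. The other 5 peaks had scaled changes between -0.46 and 0.09.

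**Figure D5:**
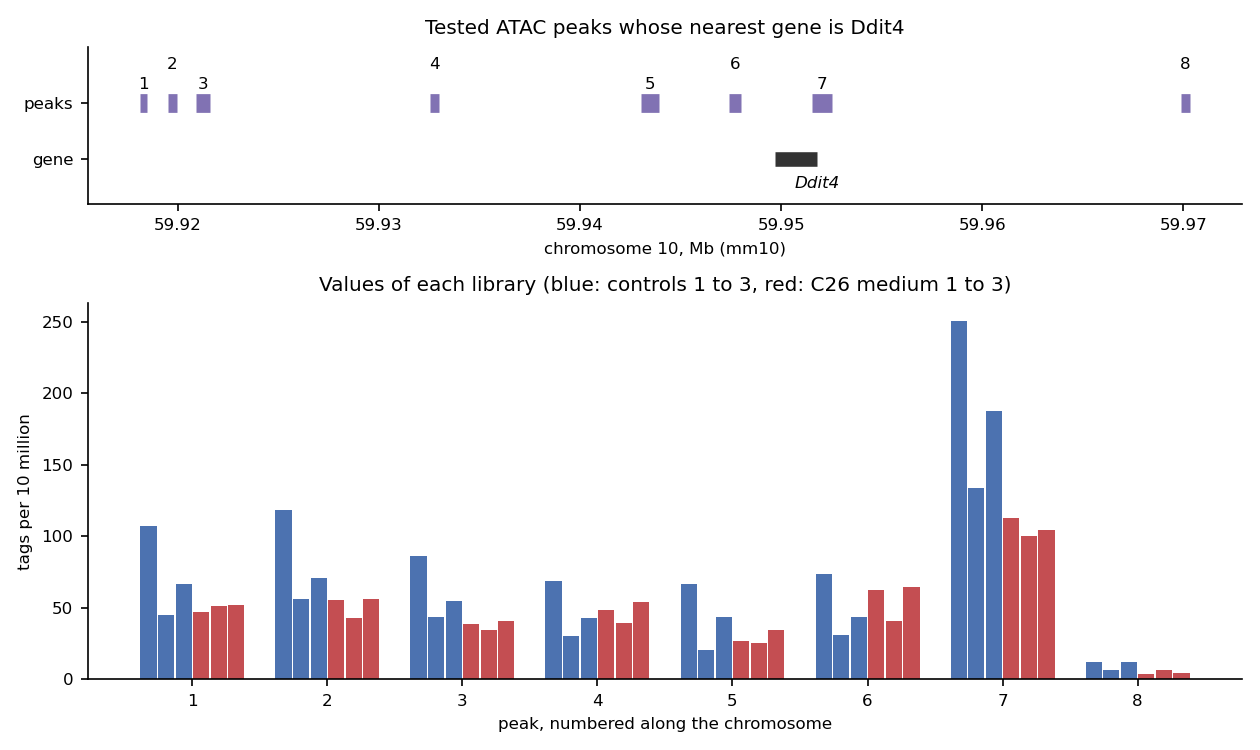
The 8 tested ATAC peaks nearest to Ddit4 and the gene's position on chromosome 10 in mm10 (top), with the tags per 10 M of each control (blue) and C26 medium (red) library (bottom). The promoter peak, number 7 in the plot, held more tags than the other peaks in every library.

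At promoters camera called 2 of 21 lists lower relative to other promoters, ATF4 and integrated stress response (adjusted p of 0.00504) and the myostatin, activin and BMP pathway (0.0290). Both calls were lost at adjusted p = 0.986 with an estimated correlation, and with quantile normalization (0.0608 and 0.0626). Of 21 promoter peaks of ATF4 and integrated stress response genes, 18 were lower on the deposited values when adjusted over the list alone and 1 over all peaks, that of Chac1 (-0.53 scaled, SE 0.09); after scaling 12 were lower over all peaks. The median change on the deposited values was -0.84 in this list and -0.69 over all 10146 promoters used. Of 19 promoters of the myostatin, activin and BMP pathway, 12 were lower on the deposited values when adjusted over the list alone and 2 over all peaks, Inhbb (-0.70 scaled, SE 0.12) and Nog, a BMP antagonist (-0.76 scaled, SE 0.17); after scaling 10 were lower over all peaks. Single promoters called lower on the deposited values in other lists were those of Irs1, an insulin receptor substrate (-0.59 scaled, SE 0.09), the chemokine gene Cxcl5 (-0.97, SE 0.15), Ndufs7 of respiratory complex I (-0.69, SE 0.11) and Acot2 (-0.63, SE 0.11). Of all 10146 promoters used, 100 were lower on the deposited values and 2215 after scaling, when every list held at least 2 lower promoters, among them 8 of 23 REDD1, mTORC1 and FOXO regulators, 7 of 19 atrophy ligases and 4 of 19 methionine cycle genes. The myostatin call was also lost with median-of-ratios scaling (0.0563) and without control 1 (0.1), control 3 (0.0548), C26 medium 1 (0.0899) or C26 medium 2 (0.131). The other 19 lists, the methionine cycle (0.726), DNA methylation (0.847) and REDD1, mTORC1 and FOXO regulators (0.672) among them, had adjusted p-values between 0.330 and 0.946. Scaled changes at the promoters of Mat2a, Ahcy, Mtr, Dnmt3a, Foxo1, Fkbp5, Fbxo32 and Atf4 were -0.36, -0.10, 0.10, -0.31, -0.25, -0.21, -0.0061 and -0.31, of which Mat2a (adjusted p = 0.00352) and Atf4 (0.00502) were called lower after scaling and 0 on the deposited values.

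Setting the assays side by side asks whether promoters and mRNA moved together across 8948 genes, although one assay used cultured myotubes with C26 medium and the other muscle of LLC mice. Col1a1 was lower in both. It had the smallest rank sum of p among genes with a scaled promoter call and an unadjusted RNA p under 0.05 in the same direction. Its mRNA had a log2 difference of -2.12 (SE 0.40) and did not pass over all genes. Tendon markers were lower in the same LLC libraries, and whether other tissue in the muscle samples had a part in the Col1a1 difference was not tested. Its promoter peak, in an intron 982 bp from the start, had a scaled change of -0.47 (SE 0.10). That peak was called after scaling (limma adjusted p = 0.000421) and not on the deposited values (0.0819). Chac1 and Inhbb had lower promoter peaks and mRNA differences of 1.37 (SE 0.31) and 1.44 (SE 0.23). Across genes, which are not independent replicates, Spearman's rho was -0.017 for promoter peaks and 0.039 for the mean of all peaks assigned to a gene. No gene was called in both assays, since limma called 0 genes in the RNA. At an unadjusted RNA p under 0.05 and scaled promoter calls, 13 genes were higher in both, with 6.94 by chance (Fisher's exact p = 0.0280). Lower in both were 20 genes, fewer than the 30.5 by chance (Fisher's exact p = 0.0288).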

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

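The tests of marrow, blood, depth, skin and tumour cells in this part were chosen after the values had been seen, and those of promoter and distal peaks before.

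The peak lists of the single ATAC libraries, which no comparison used, held 915 regions present in all 3 C26 medium lists and in no control list, against 644 present in all 3 control lists and in no C26 list. This difference between the groups set them apart for a closer look, and it was not tested. Of the 915 regions 864 were tested as peaks, and after scaling 795 were higher and 0 lower. Of the 644 control regions 630 were tested, and 1 was higher and 312 lower. The regions were picked by their presence in the lists of the same libraries, so these directions were set by the choice and are no separate evidence.

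Genes of marrow, blood and bone differed widely between the muscle libraries, with PBS 3 above PBS 1 by a median log2 of 3.43 for granulocyte precursors, 4.73 for erythroblasts, 1.35 for osteoblasts and 0.659 for osteoclasts. Bone with marrow in some muscle samples predicted at least 1 in all 4 lists, and the osteoclast list missed that. The 3 of its 8 genes that passed the filter, Acp5, Ctsk and Tcirg1, stood at 5.15, 15.4 and 6.46 FPKM in PBS 1. In PBS 3 they stood at 48.8, 33.6 and 25.2 FPKM. Its other genes lay below the filter, where log2(FPKM + 1) moves little, so the miss cannot decide the question. This explanation cannot be told apart from others. Blood neutrophils alone predicted an osteoblast difference under 0.5, and the measured one was 1.35. PBS 3 had 1.14 times the reads of PBS 1, too little for depth to give such differences. These predictions were written after the values had been seen, so none is a separate test. Whether other tissue was sampled with the muscle, and which, stays open.

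The epidermis median was 4.19, 1.92 and 2.48 in LLC 1 to 3 and 0.14, 1.07 and 2.90 in PBS 1 to 3, so PBS 3 lay above 2 of the 3 LLC libraries. Skin in the samples predicted a rise of at least 1 in each LLC library over PBS 1 and PBS 2, and the smallest rise was 0.855, so skin cannot be told apart from other sources. Tumour cells predicted a rise of the cell cycle list, whose median was -0.73, but that list also follows the marrow genes, so this cannot be told apart either.

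Promoter peaks lay below distal peaks after scaling, by -0.249 in the median. Within 5 classes of signal strength the difference stayed in every class, from -0.230 to -0.191, which argues against signal strength as its whole source. Some classes fell short of the -0.2 written before, so a smaller part of signal strength in it cannot be told apart. Leaving out control 1, which had the most tags in peaks, left -0.256, which argues against that library as the source. Control 1 against controls 2 and 3 gave -0.0141, which argues against the share of tags in peaks. Whether a change of the cells or of the preparation of the C26 libraries lies behind the difference stays open.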

How the results depend on the processing

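Among single results outside the main counts 3166 comparisons stayed on the same side of the threshold, 46 became stronger, 62 weaker, 6 moved and 3 reversed with a call. Lists with no call also changed direction: with 1 muscle library left out the fast-fibre, glycolysis, neutrophil and Schwann lists pointed up in 3 of 6 fits, oxidative phosphorylation in 4, ATF4, circadian, adipocyte and myogenic lists in 5, and fibro-adipogenic progenitors in 1. With 1 ATAC library left out the DNA methylation and glucocorticoid promoter lists pointed up in 1 of 6 fits and the matrix and cell cycle promoter lists in 2. The fat oxidation, endothelial, glucocorticoid, IL-6, slow-fibre, proteasome, autophagy, heat shock and tendon lists kept their calls with any 1 library left out. Fits with marrow or skin covariates, scaled ATAC values with further settings, and the scaled odds ratio were chosen after values had been seen. Unless a reason is given, the cause was not tested.

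In the RNA, 1 gene was higher at an adjusted p under 0.1, 1 with a mean FPKM of at least 5 (fewer genes tested), 2 with TPM, 1 with median-of-ratios scaling, 1 with quantile normalization and 3 with the marrow covariate. Without a filter 3 lists were lower. An estimated correlation left 0 lists higher and 0 lower, and fry 2 and 0. The atrophy ligases had an adjusted p of 0.0683 with TPM, 0.0691 with median-of-ratios scaling, 0.522 with an estimated correlation and 0.261 with fry; the REDD1, mTORC1 and FOXO list had 0.522 and 0.230. The fast-fibre list turned higher with quantile normalization (0.0175).

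With 1 muscle library left out, 9 to 17 lists were higher and 2 to 6 lower, and the Ddit4 log2 difference ran from 0.88 to 1.30. Adjusted p ran from 0.00207 to 0.348 for the atrophy ligases, 1.85e-05 to 0.0564 for the REDD1 list, 0.00545 to 0.814 for the methionine cycle, 0.205 to 0.564 for DNA methylation and 0.240 to 0.814 for ATF4. Glycolysis ran from 0.0227, called higher without PBS 1, to 0.967, and the neutrophil list from 0.0173, called higher without LLC 3, to 0.786.

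In the ATAC data an adjusted p under 0.1 gave 670 higher and 2825 lower, a mean of at least 20 gave 133 and 338, no trend 710 and 1892, median-of-ratios scaling 6368 and 4753, quantile normalization 5595 and 5426, and edgeR 6571 and 4783. The last 3 remove the shift between the groups. At Ddit4, median-of-ratios scaling called 2 peaks higher and 1 lower and quantile normalization 2 and 0. Promoter lists called lower were 1 with median-of-ratios scaling, 0 with quantile normalization and 0 with an estimated correlation. Scaled higher peaks fell to 4179 with a mean of at least 20, where fewer peaks were tested. The odds ratio of lower peaks turned to 2.64 with scaling, and rho to 0.0394 over all peaks of a gene. With 1 library left out, 92 to 1954 peaks were higher and 32 to 19854 lower, 0 to 6 were lower at Ddit4 and 1 to 2 promoter lists lower; after scaling 5143 to 5770 were higher, 3189 to 4206 lower and 0 to 1 lower at Ddit4.

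The replicate numbers do not pair the samples: correlations of deviations were -0.09, 0.60 and -0.60 in the RNA and -0.01, 0.01 and -0.02 in the ATAC, and samples did not all correlate best with their own number. With the number as a block, 0 genes, 13 lists higher and 7 lower, 415 and 656 peaks, and 6364 and 4610 scaled peaks were called, with folate (0.0450), myostatin (0.0405) and B cell (0.00268) lists added. Simulation with 3 libraries per group recovered 42 of 100 genes changed by a log2 of 2; depth was not varied, so its part in that limit was not tested.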

Other observations

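All tests of this part except the regroupings of the libraries were chosen after the values had been seen.

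Of all distal peaks 22.9% were higher after scaling, and the genes with the most such peaks were ranked by their count, which favours genes with many peaks; no test compared the counts with chance. Among them, 14 of 21 distal peaks nearest to Cops8, 12 of 26 at Bmper, which binds BMPs, 12 of 14 at Ism1 and 9 of 15 at Pla2g4a were higher. At Il6, the gene of interleukin-6, 6 of 7 distal peaks were higher after scaling. None of the 7 was called on the deposited values (limma adjusted p from 0.0582 to 0.363). They lay -125608 to -5881 bp from the start and were assigned to Il6 only as the nearest gene. The strongest, on chromosome 5 (30000842 to 30001423, mm10), had a scaled log2 change of 1.81, while the Il6 promoter peak had -0.09. Among genes with the most lower peaks were Cln8 (7 of 18), Ncam1 (6 of 15) and Inhbb (5 of 10). These genes were chosen after their values were seen.

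In every LLC muscle library the erythroblast median lay further below the granulocyte precursor median than in every PBS library, at -4.08, -2.31 and -1.26 against -0.54, -0.29 and -0.27. The group means differed by -2.19. The prediction for this ratio was written after the same values had been seen, so it tested nothing, and no conclusion on precursor numbers is drawn. In PBS 1 and LLC 3 both lists lay near the floor, with medians of 0.45 and 0.99 in PBS 1 and 0.27 and 1.53 in LLC 3.

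The hypothesis that cytokine targets gained distal peaks as a group was tested with camera over distal peaks. The NF-kB list had an adjusted p of 0.893 and the IL-6 and STAT3 list 0.893, so a gain of the groups cannot be told apart from none. Of their distal peaks 30.3% and 27.9% were higher after scaling, against 22.9% of all distal peaks.

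Regrouping the 6 libraries of an assay gives 10 splits, too few for a share under 0.05. Every other split mixes libraries of both groups, so a difference between the groups widens its spread and can lower its count. A low count in the other splits is therefore no measure of what chance alone gives. As large a result as the real one came from 2 splits for RNA genes at an unadjusted p under 0.05 (991, highest other 3266), 4 for gene lists (17, highest other 21), 1 for deposited ATAC peaks (1132, highest other 0), 1 for scaled ATAC peaks (11121, highest other 0) and 1 for promoter lists (2, highest other 1). The split with 3266 genes sets PBS 1, LLC 1 and LLC 3 against the rest and points to a structure of the muscle samples other than the treatment.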
